A study of Mus musculus with 198 samples.

How the data were processed

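Bisulfite libraries of mouse cortex, striatum, hippocampus, cerebellum, liver and cultured cortical neurons were analysed from 2 tables. Per the submitters' processing notes, BS-Seeker2 and bedtools were used with the mm9 genome; no versions are given in the sources used here. The deposited values are fractions of methylated cytosines: 1 table holds 1 fraction per library for CA, CG, CC, CT and the unmethylated lambda spike-in, and the other 1 fraction per gene or enhancer in each of 8 deep libraries. A further 8 columns hold the authors' group means and were not used here. Fractions were multiplied by 100 to give percent. No table used here gives counts or coverage, so coverage minima, weights and counting intervals were not applied.

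Groups came from the labels. Cultures were chosen by the submitters, per the labels' protocols, for matched expression of the construct messenger RNA. There were 88 culture libraries with a group, 8 untransduced wild-type libraries, and 2 libraries whose title and genotype label disagree, which entered no comparison. Libraries of an animal that held equal fractions within 1e-09 were counted once (3 libraries). The CA cell of 1 WT striatum equals its lambda cell and was treated as missing. Lambda was absent in 5 libraries and exactly 0 in 2; these zeros were treated as missing in comparisons of lambda, a choice made after the lambda difference had been seen, and both results are given. Lambda exceeded CC in all 183 libraries with a lambda value above 0 (medians 0.488% and 0.298%), so lambda overstates the background in CC, and deposited values were used uncorrected.

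Single values were compared by two-sided permutation tests of the difference in means, exact where a group held fewer than 10 values and with 100000 resamples otherwise (seed 1), in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Benjamini-Hochberg adjustment was applied per context over 6 ages, 4 tissues and 18 culture comparisons, and over the 4 deep means of both contexts together. Standard errors of differences are given in place of intervals. Comparison of the WT construct with no virus was added later, outside the family of 18.

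Genes and enhancers were tested on the fraction with limma 3.58.1 in R 4.3.3 (moderated by eBayes with a trend), because no counts were given, with a threshold of 0.05 on the adjusted p and only regions measured in all 8 libraries. Gene lists were tested with fry and camera for lists of at least 5 measured members. Named genes followed a rule fixed before the data were examined: Dnmt3a; the 10 largest falls and 5 largest rises among genes that passed and whose groups did not overlap; and up to 3 passing members per list, or else the member with the largest difference. Enhancers have no coordinates in the table used here, so 2 falling and 2 rising ones are named. The values of some genes that these rules or comparisons name are not reported here. Gene symbols are those of the table; 24888 of 34193 matched a symbol and 3066 more a synonym in a RefSeq table of GRCm38.p6, used for names only. Length bins were not run, since no mm9 annotation was used here.

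The methods were tested on simulated data. Over 21302 genes, limma recovered 42 of 100 mCA values halved and 91 of 100 raised 3-fold, with 7 other calls; over 32614 enhancers it recovered 9 and 86, with 2 other calls. For mCG, raised 1.5-fold, it recovered 95 and 84 of 100 genes and 67 and 63 of 100 enhancers. With every region halved, it recovered 81.1% of genes and 65.4% of enhancers in mCA. An isolated halving of enhancer mCA was therefore mostly missed at this sample size. Permutation tests of 4 against 4 values without a difference gave p under 0.05 in 2.9% of 1000 runs.

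Alternatives were each library as its own sample, lambda subtracted, each sex alone, each animal or library left out, permutation within title number or title format, culture codes averaged, medians, a logit scale, library medians removed, and sex as covariate. Sequencing instrument in the labels coincides with sex in the deep set, balanced over genotype.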

Results

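Cytosine methylation was measured by whole-genome bisulfite sequencing in mice lacking 1 copy of Dnmt3a, which encodes a DNA methyltransferase, and in wild-type (WT) mice. Heterozygous knockouts are called hKO here. Of 198 samples, 190 were shallow libraries, with a labelled coverage of 0.01 to 0.03 genome equivalents, and 8 were deep cortex libraries, labelled 6.4 to 7.8. The shallow set held 92 tissue libraries from 55 animals and 98 libraries of cultured cortical neurons. Among the tissue libraries, 3 held the same values as another library of their animal within 1e-09 and were counted once, which left 89. The number of cytosines behind each value is unknown, so no counting interval was computed. Methylation is given as the percentage of cytosines called methylated at CA sites (mCA), the commonest methylated non-CG context in neurons, and at CG sites (mCG). Libraries of 1 animal were averaged, so n counts animals in tissues.

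The first question was whether loss of 1 Dnmt3a copy changes global methylation in adult cortex. At 8 weeks mCA was 1.34% ± 0.102 (SD, n = 7) in hKO cortex and 2.43% ± 0.152 (SD, n = 11) in WT cortex. The difference of -1.10 percentage points (SE 0.0598) left hKO cortex with 54.9% of the WT level, and every hKO animal, from 1.22% to 1.45%, lay below every WT animal, from 2.20% to 2.72%. The exact two-sided permutation test gave p = 3.14e-05, the smallest that 31824 arrangements allow, and 0.000189 after adjustment over 6 ages. mCG was 68.0% ± 3.38 (SD, n = 7) in hKO and 71.5% ± 5.71 (SD, n = 11) in WT cortex, and this difference of -3.51 points did not pass the exact permutation test (p = 0.161, adjusted 0.400). The unadjusted mCG result depended on WT animal 726: without it the difference was -4.80 points, with an exact permutation p = 0.0235, which did not pass over 6 ages (adjusted 0.141).

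The age series asked when the difference between genotypes appears. mCA was near 0.3% in cortex of both genotypes at birth and in WT cortex it was 0.458% ± 0.0592 (SD, n = 3) at 1 week, 1.32% ± 0.0513 (SD, n = 5) at 2 weeks and 1.96% ± 0.405 (SD, n = 5) at 4 weeks, before the 8-week level of 2.43%. In hKO cortex it was 0.3003% ± 0.0486 (SD, n = 3) at birth, 0.363% ± 0.0501 (SD, n = 3) at 1 week, 0.812% ± 0.0307 (SD, n = 3) at 2 weeks, 1.54% ± 0.559 (SD, n = 3) at 4 weeks and 1.30% ± 0.0917 (SD, n = 3) at 20 weeks. The WT values at birth and at 20 weeks were 0.292% ± 0.0426 (SD, n = 5) and 2.36% ± 0.0943 (SD, n = 3). Exact permutation tests gave p = 0.821 at birth, p = 0.2 at 1 week, p = 0.0179 at 2 weeks (adjusted 0.0536), p = 0.375 at 4 weeks and p = 0.1 at 20 weeks. The 4-week difference of -0.424 points was -0.746 without the library labelled hKO 008-4, -0.235 without hKO animal 006-4 and -0.926 without 008-3 and 008-4 (2 hKO and 4 WT animals, exact permutation p = 0.0667, the smallest possible, chosen after the data had been seen). With 3 animals against 3, as at 1 and 20 weeks, no exact p can go below 0.1.

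Over all ages, with genotype permuted within age, hKO cortex differed from WT cortex by -0.632 points in mCA (22 hKO and 32 WT animals, p = 1e-05, the smallest that 100000 resamples give). The genotype difference in points itself changed with age (permutation of residuals, F = 12.8, p = 1e-05, again the smallest possible). Uncorrected, the hKO level was 102.8% of WT at birth, 79.3% at 1 week and 61.7% at 2 weeks. It was 78.3% at 4 weeks and 54.9% at both 8 and 20 weeks. With the CC level subtracted, chosen after the data had been seen, the hKO level was 74.6% of WT at 4 weeks. At 1, 2, 8 and 20 weeks it was from 45.2% to 51.7%, untested, so the change in points does not show a change in proportion at these ages. At birth mCA lay only 0.00886 points above CC in hKO (SD 0.0208) and 0.0174 in WT cortex (SD 0.0235), so no ratio can be read there. mCG differed by -2.36 points over all ages (permutation p = 0.0117), with no detected change with age (p = 0.957), and at no single age did it pass the test. In females alone the mCG difference was -1.92 points (permutation p = 0.149). At 4 weeks the library labelled WT 008-3 held 1.24% mCA and the library labelled hKO 008-4 held 2.18%, each near the animals of the other label. Without this pair the pooled mCA difference was -0.695 points. WT mCA rose from birth to 1 week, from 1 to 2 weeks and from 4 to 8 weeks. The steps into and out of 4 weeks include 008-3. The other 4-week WT animals, at 2.06% to 2.20%, all lay above the 2-week WT animals, at 1.26% to 1.39%. Steps without 008-3 were not tested. In WT cortex the exact permutation tests of successive ages gave adjusted p = 0.0298 from birth to 1 week, p = 0.0298 from 1 to 2 weeks, p = 0.0595 from 2 to 4 weeks, p = 0.00114 from 4 to 8 weeks and p = 0.431 from 8 to 20 weeks; these steps were compared after the data had been seen.

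**Figure D1:**
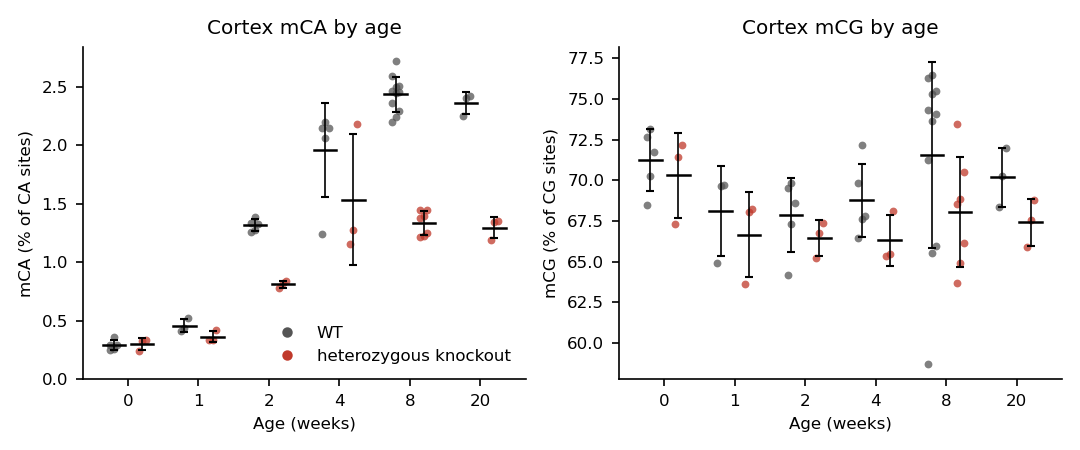
Cortex mCA (left) and mCG (right), in percent of sites, by age in weeks; points are animals, black bars the mean and SD of each genotype, and the mCG axis does not start at 0. mCA of hKO and WT animals overlaps at birth and is apart at 8 weeks, where the means are 1.34% and 2.43%.

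Another 4 tissues of 8-week animals asked whether the lower mCA is brain-wide and whether liver shares it. mCA was lower in every hKO animal than in every WT animal in each tissue. It was 1.24% against 2.12% in striatum, 0.910% against 1.51% in hippocampus, 0.702% against 1.11% in cerebellum and 0.299% against 0.382% in liver. The hKO level was 58.4% of WT in striatum, 60.4% in hippocampus, 63.5% in cerebellum and 78.2% in liver. These ratios depend on the background: with the CC level subtracted, a step chosen after the data had been seen, they were 52.7%, 52.5%, 51.3% and 30.4%, and the order of the tissues changed. Liver mCA lay only 0.0332 points above CC in hKO and 0.109 in WT. It lay below the mean lambda level of these livers, 0.563% in hKO and 0.524% in WT. The liver ratios therefore rest on values near the background. The exact permutation p was 0.0667 in hippocampus, cerebellum and liver (2 hKO and 4 WT animals) and 0.1 in striatum (2 and 3 animals), the smallest each design allows, so none could pass 0.05. The CA value of 1 WT striatum repeated its lambda value and was left out. mCG differed by -2.85 points in striatum, -2.06 in hippocampus and -3.34 in cerebellum (exact permutation p = 0.0667 each), and by -0.875 in liver (p = 0.8). Within the same animals the mCA difference between genotypes in cortex minus that in the other tissue was -0.173 points for striatum (exact permutation p = 0.3), and -0.469 for hippocampus, -0.663 for cerebellum and -0.983 for liver (p = 0.0667 each, the smallest possible), so none passed. In cerebellum at 20 weeks, with 1 animal per genotype and no test, mCA was 0.721% in hKO and 1.32% in WT, and the only 3-week WT cortex held 2.08%.

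**Figure D2:**
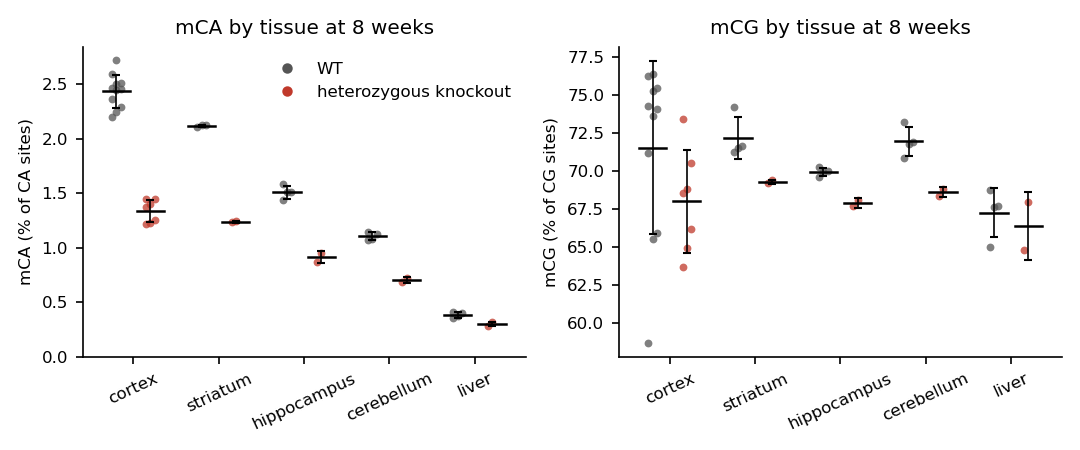
mCA (left) and mCG (right), in percent of sites, in 5 tissues of 8-week mice; points are animals, black bars the mean and SD, and the mCG axis does not start at 0. In every brain region the hKO animals lie below the WT animals in mCA, and in liver both genotypes lie under 0.5%.

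Cultured cortical neurons asked how far DNMT3A constructs return mCA to neurons without Dnmt3a. Knockout cultures held 0.495% mCA ± 0.0694 (SD, n = 10), against 0.859% ± 0.225 (SD, n = 10) in cultures without virus. With the WT construct mCA was 1.12% ± 0.330 (SD, n = 13). Among constructs with an altered protein, G532S reached 0.732% ± 0.140 (SD, n = 7), V665L 0.8289% ± 0.373 (SD, n = 8) and Y735C 0.941% ± 0.297 (SD, n = 11). W297del held 0.411% ± 0.0279 (SD, n = 5), S312fs11x 0.470% ± 0.0828 (SD, n = 4), M548K 0.440% ± 0.0445 (SD, n = 6), R749C 0.543% ± 0.142 (SD, n = 7) and P904L 0.599% ± 0.181 (SD, n = 7).

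In permutation tests adjusted over 18 comparisons, the WT construct (adjusted p = 0.000463), G532S (0.000463), V665L (0.00506) and Y735C (0.00036) lay above knockout. S312fs11x, M548K, R749C and P904L did not differ detectably from knockout (adjusted p = 0.574, 0.132, 0.393 and 0.132, exact permutation). W297del differed from knockout by -0.0842 points (exact permutation, adjusted p = 0.0330). This call was lost within title format (adjusted p = 0.213) and without any 1 of W297del replicates 1, 2, 4 and 5 (adjusted p = 0.0899, 0.0674, 0.0524 and 0.0644). The sign turned to 0.0276 points with lambda subtracted. Against the WT construct, V665L and Y735C were not detectably lower (permutation, adjusted p = 0.114 and 0.212; V665L was lower without its replicate 3, adjusted p = 0.0336), whereas the other 6 constructs were, with differences from -0.384 points for G532S (adjusted p = 0.0181) to -0.705 for W297del (0.000463). With medians in place of means, S312fs11x, G532S and P904L no longer passed against the WT construct (adjusted permutation p = 0.0626 each). Knockout lay below cultures without virus (adjusted p = 0.000463). V665L was above knockout with adjusted p = 0.0509 when libraries sharing a culture code were averaged. No mCG comparison passed, the smallest adjusted permutation p being 0.813. The labels do not say whether libraries with one culture code are separate cultures, so these p-values measure the spread between libraries.

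**Figure D3:**
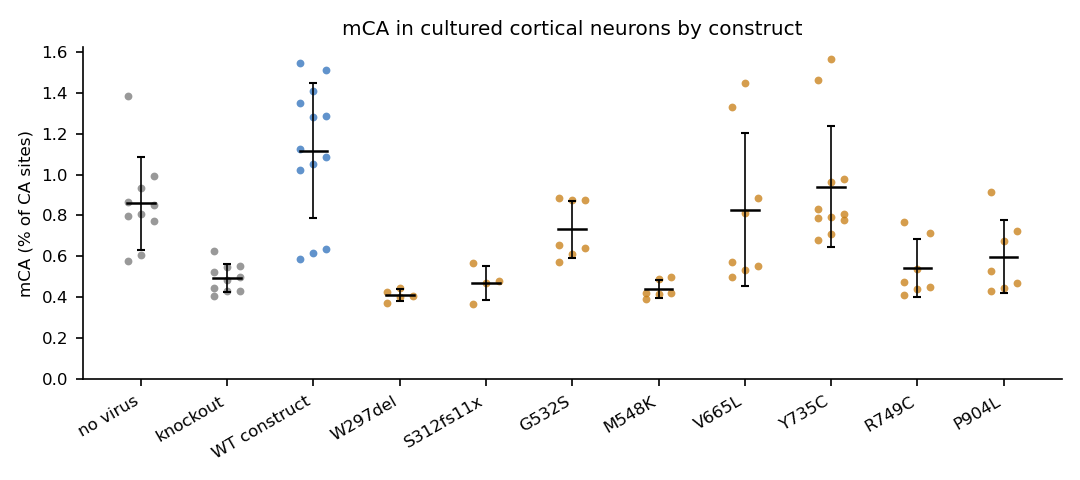
mCA of cultured cortical neurons, in percent of CA sites, by construct; points are libraries and black bars the mean and SD. The WT construct libraries range from 0.585% to 1.55%, and the knockout libraries from 0.407% to 0.626%.

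In untransduced wild-type neurons mCA rose with time in culture, from a mean of 0.549% at day 4 to 0.578% at day 7, 0.808% at day 10 and 1.14% at day 12, with 2 libraries per day. Over the 8 libraries Pearson's r was 0.898 (exact permutation p = 0.00357) and Spearman's rho 0.878 (p = 0.0103), and r was 0.952 without the 2 libraries farthest from the median day, both of day 4. mCG changed from 77.9% at day 4 to 79.8% at day 12, with r = 0.765 (exact permutation p = 0.0274, the adjusted value over both contexts being the same) and rho = 0.878 (p = 0.0103). The adjusted p of the mCA r was 0.00714.

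Deep libraries of 4 hKO and 4 WT cortices measured genes and enhancers. Over 21302 genes, mean mCA was 1.25% ± 0.130 (SD, n = 4) in hKO and 2.21% ± 0.263 (SD, n = 4) in WT cortex, a difference of -0.960 points. Over 32614 enhancers it was 1.32% ± 0.135 (SD, n = 4) and 2.36% ± 0.286 (SD, n = 4). Both exact permutation tests gave p = 0.0286, the smallest that 35 splits allow, and 0.0571 after adjustment over 4 tests. mCG of genes was 73.9% in hKO and 76.2% in WT (exact permutation p = 0.171), and mCG of enhancers 57.7% and 61.7% (p = 0.0571). The difference of enhancers minus that of genes was -1.66 points in mCG and -0.0859 points in mCA. Both exact permutation tests gave p = 0.0286, again the smallest possible, and both comparisons were added after the data had been seen.

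Dnmt3a itself carried 0.761% mCA in hKO and 1.25% in WT cortex (limma, adjusted p = 0.0115), and its mCG was 57.6% and 63.2% (limma, adjusted p = 0.476). Gene-body methylation does not check the deletion. mCA fell in 15369 of 21302 genes, 72.1%, and rose in 7 (limma on the fraction, adjusted p under 0.05). Counts of falls and rises of genes and enhancers cover only those that passed. A lower mean in hKO cortex was held by 97.1% of genes. In 13759 genes, 64.6%, all 4 hKO animals lay below all 4 WT animals, where chance gives 1.43%. The median gene kept 56.6% of its WT mCA. Among the largest falls, Gm2670 went from 9.04% to 3.61%, Gngt1, which encodes a photoreceptor G protein subunit, from 9.22% to 3.86%, Cml2 from 6.99% to 1.91%, and Gm11212 from 7.48% to 2.43%. Sox9, a transcription factor of glial development, fell from 7.30% to 2.46% (limma, adjusted p = 0.00966). WT animals ranged from 4.32% to 11.6% in Sox9 and from 6.45% to 13.7% in Gm2670, but from 8.18% to 9.76% in Gngt1. Ranking in points favours genes with a high or variable level, and relative loss was not ranked. The same rule named 2810030E01Rik, Gm16270, 9230117E06Rik and Gm15634, and B130006D01Rik, which is listed at 0 in all 4 hKO libraries. Nubp2, an iron-sulfur cluster assembly factor, rose from 0.358% to 1.16%, and Gm15051 from 0.142% to 0.538%; the other 5 higher genes, named after their values were seen, were C1ql4, which is listed at 0 in all WT libraries, Gm14974, Mrgpra6, Prss30 and Vmn2r-ps40. The number of higher genes was 21 without 651-3, 4 without 695, 13 without 694, 12 without 046-2 and 3 without 047-2. Males alone gave 13500 lower genes and females alone 7841. When each library's median was subtracted, 5283 genes were lower and 6523 higher, so the calls describe absolute levels against a median shift of -0.907 points.

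Of the 17 gene lists fixed before the data were examined, mCA fell in 15 (limma fry, adjusted p under 0.05). List members are counted as fallen where limma passed over all genes, as it did for 72.1% of all genes. Fry takes each list by itself, and against other genes, most of which also fell, camera put 3 lists lower with a preset correlation and 0 with an estimated one. All 50 neuronal adhesion and axon guidance genes fell, 50 of them also when adjusted over the list alone, with Auts2 going from 4.46% to 2.52%, Dscaml1 from 2.95% to 1.60% and Epha3 from 2.93% to 1.60%. All 11 endothelial markers fell (11 adjusted over the list alone), Pecam1 from 4.44% to 2.38%, as did 13 of 14 astrocyte markers (13), Aldh1l1 from 4.22% to 2.24% and Fgfr3 from 4.40% to 2.39%. Oligodendrocyte markers fell in 15 of 17 (15), Pdgfra from 4.35% to 2.42%, and microglia markers in 10 of 13 (10), Csf1r from 2.67% to 1.30%. Excitatory neuron markers fell in 12 of 20 (12), Bcl11b from 3.75% to 2.05%, and inhibitory neuron markers in 12 of 18 (12), Pvalb from 4.03% to 2.08% and Reln from 3.51% to 1.93%. Synaptic genes fell in 31 of 40 (32), Nrxn3 from 2.21% to 1.21%, activity-regulated genes in 10 of 17 (10), and autism and overgrowth chromatin genes in 19 of 29 (19), Ezh2 from 2.68% to 1.44%. With library medians subtracted, fry called the synaptic and chromatin lists higher. As a share of the mean over all genes, however, the synaptic list was at 61.4% in WT and 63.7% in hKO (exact permutation p = 0.343). The chromatin list was at 73.1% in WT and 75.6% in hKO (exact permutation p = 0.514). DNA methylation machinery fell in 11 of 15 (11), Dnmt3b from 4.18% to 2.16%. Fry called this list higher too with medians subtracted, but its share of the mean over all genes was 83.00% in WT and 83.05% in hKO. Without that subtraction, fry had an adjusted p of 0.00288 for the machinery list and for excitatory markers, and 0.000699 for astrocyte and endothelial markers. Imprinted genes fell in 19 of 25 (20), Igf2r from 2.95% to 1.55%.

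Homeobox regulators fell in 28 of 91 (26 adjusted over the list alone), Meis1 from 4.44% to 2.52% and Pax6 from 3.62% to 1.80%, olfactory receptor genes in 39 of 134 (32), Olfr155 from 4.61% to 1.38%, and genes with a ribosomal protein prefix in 19 of 62 (11), whose named members Rps6ka1, Rps6ka2 and Rps6ka5 encode S6 kinases, not ribosomal proteins. Clustered protocadherins fell in 1 of 19 (0), Pcdhga11 from 1.13% to 0.651%, and vomeronasal receptor genes in 26 of 132 (5), Vmn2r3 from 2.03% to 1.03%; fry did not pass for these lists (adjusted p = 0.330 and 0.229). Members that did not pass mostly had lower means too. The hKO mean was lower in 76 of 91 homeobox, 114 of 134 olfactory and 45 of 62 ribosomal prefix genes. It was lower in 12 of 19 protocadherin and 117 of 132 vomeronasal genes. The number of lists called lower by fry was 14 without hKO animal 694, 13 without 046-2 and 13 without 047-1. The olfactory list was lost without each of these animals (adjusted p = 0.0705, 0.0751 and 0.0759), and the ribosomal prefix list without 046-2 and 047-1 (0.0525 and 0.0601). With library medians subtracted, fry called 6 lists lower and 8 higher, the higher ones being methylation machinery, homeobox, protocadherin, synaptic, chromatin, olfactory, vomeronasal and ribosomal prefix genes. These calls are in points after an equal shift of every gene. As a share of the mean over all genes, no list differed between genotypes after adjustment (exact permutation, smallest adjusted p = 0.194). Excitatory and olfactory shares were higher in hKO (unadjusted exact permutation p = 0.0286, the smallest possible). Shares were not among the planned tests. Against other genes, camera with a preset correlation of 0.01 put adhesion (adjusted p = 1.36e-05), endothelial (0.0197) and astrocyte (0.0211) genes lower, and none held with an estimated correlation (adjusted p = 0.906, 0.719 and 0.741). It put homeobox, protocadherin, olfactory, vomeronasal and ribosomal prefix genes higher, and none held with an estimated correlation (adjusted p = 0.337, 0.0677, 0.337, 0.510 and 0.256), although protocadherins passed without hKO animal 651-2 (adjusted p = 0.0499).

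Enhancer mCA fell in 15926 of 32614 regions and rose in 2 (limma, adjusted p under 0.05), and the median enhancer kept 55.96% of its WT level. Whether or not they passed, 97.8% of enhancers had a lower mean in hKO cortex. The enhancer listed as enh.39412 went from 9.07% to 3.88% and enh.5627 from 7.58% to 2.43%, and enh.39670 rose from 0.745% to 1.58% and enh.24280 from 0.302% to 0.911%. All 4 hKO animals lay below all 4 WT animals in 41.2% of enhancers, where chance gives 1.43%. With library medians subtracted, 43 were lower and 237 higher. Neither sex alone gave a call (limma, 0 enhancers, with 11595 in males and 11216 in females at an unadjusted p under 0.05). The count of lower enhancers was 9697 without WT animal 651-3, 7804 without hKO animal 694, 7001 without hKO animal 046-2 and 8396 without hKO animal 047-1.

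mCG passed the test at no gene of 21060 and no enhancer of 32600 (limma, 0 calls in either direction), although 2195 genes and 4381 enhancers had an unadjusted p under 0.05 and 84.0% of genes had a lower mean in hKO cortex. The count was 1 gene without hKO animal 651-2, 1 gene without WT animal 047-2, and 1 enhancer without 047-2. The gene with the smallest p, Gm4793, held 67.1% in hKO and 81.3% in WT (limma, adjusted p = 0.195), and was named after its values were seen. Values of single list members were Mbd4 75.4% and 82.5%, Dlk1 44.6% and 55.4%, Hoxc5 26.8% and 44.7%, Pcdhb9 47.05% and 81.2%, Fezf2 19.4% and 34.1%, Maf 69.9% and 77.3%, Mbp 63.9% and 69.0%, Sox9 25.3% and 32.2%, and Aif1 58.6% and 66.0%, for hKO and WT. For Esam they were 50.3% and 59.8%, for Nlgn2 59.1% and 70.4%, for Slit1 64.7% and 71.0%, for Jun 31.2% and 69.3%, for Arid1b 64.1% and 69.98%, for Olfr348 61.1% and 86.8%, for Vmn1r58 66.5% and 77.5%, and for Rpl14 84.7% and 60.7%. In Pcdhb9 the hKO library 047-1 was listed at 0. The genes named for a list are its members with the largest difference, a choice that favours variable genes. None passed limma over all genes. The SD over WT animals was 20.7 points in Jun, 27.6 in Hoxc5 and 26.9 in Pcdhb9, but 1.85 in Slit1. The mean difference of the activity-regulated list, which holds Jun, was -5.05 points. Without a block for pairs, no list passed fry in mCG. The smallest adjusted p was 0.150 for homeobox regulators, which passed without WT animal 046-1 (adjusted p = 0.0118). With the planned replicate block, fry called 12 lists lower in mCG. That block gave 0 mCG genes by limma, with 6634 at an unadjusted p under 0.05. The list result in mCG therefore depends on whether the animals are treated as pairs. Among activity-regulated genes 2 were lower in mCG when adjusted over the list alone, and 0 over all genes. For vomeronasal receptor genes fry pointed up while the mean and median differences were -0.0402 and -0.122 points. Camera with the preset correlation put adhesion genes lower (adjusted p = 0.00640) and protocadherin, olfactory and vomeronasal genes higher (0.00939, 7.11e-07 and 6.16e-13), and none held with an estimated correlation (adjusted p = 0.943, 0.513, 0.513 and 0.513).

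The loss was also compared over regions grouped by their mean level in all 8 libraries. Genes in the lowest quartile of mCA went from 0.742% in WT to 0.490% in hKO, and those in the highest quartile from 3.94% to 2.19%. The difference in loss was -1.49 points in genes and -1.33 in enhancers (exact permutation p = 0.0286, the smallest possible). In relative terms genes lost 33.9% in the lowest and 44.3% in the highest quartile, which was not distinguishable by exact permutation (p = 0.429). With the CC level of 8-week cortex subtracted, a step chosen after the data had been seen, the losses were 41.6% and 46.18% in genes (exact permutation p = 0.914) and 47.14% and 47.00% in enhancers (p = 1). That level was 1 constant per genotype, 0.360% in WT and 0.267% in hKO, from all shallow 8-week cortex libraries. Among the deep animals, hKO 694, 046-2 and 047-1 held 0.348%, 0.347% and 0.272% CC in shallow libraries. WT 695, 046-1 and 047-2 held 0.376%, 0.381% and 0.305%. The relative loss of the lowest quartile therefore depends on the background chosen, and the order of quartiles in relative loss is not settled. mCG showed the opposite order in points: genes of the lowest quartile differed by -3.07 points and those of the highest by -1.28, and enhancers by -4.93 and -2.95. The exact permutation test of highest against lowest gave p = 0.0286 in genes and in enhancers, and 0.0571 in enhancers without hKO animal 047-1.

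**Figure D4:**
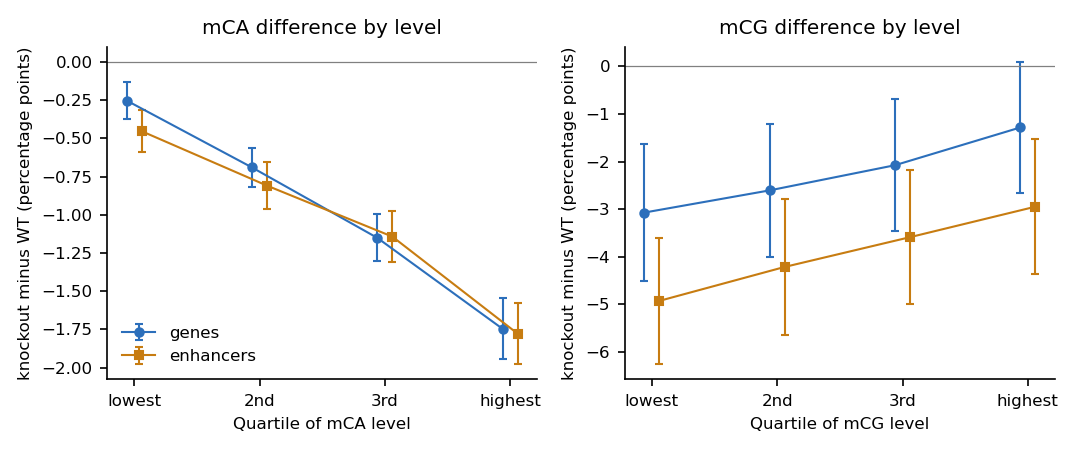
hKO minus WT difference in mCA (left) and mCG (right), in percentage points, by quartile of the mean level over all 8 deep libraries; points are differences of genotype means (n = 4 each) and bars their standard errors. The mCA difference of genes runs from -0.252 to -1.75 points, and that of mCG from -3.07 to -1.28.

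For 6 animals with both kinds of library, deep gene mCA was lower than shallow genome-wide mCA with differences from -0.445 to -0.0996 points, and the genotype difference was -0.892 points in deep and -1.01 in shallow libraries. The animals fall into 2 genotype clusters, so no correlation was computed.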

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

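The tests of explanations and the counts over other splits of the samples were all chosen after the results had been seen, whereas the rule for samples far from their group and the test of the age difference were fixed before.

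In 4-week cortex, the library labelled WT 008-3, at 1.24% mCA, lay far from the other 4 WT animals (2.06% to 2.20%). Incomplete bisulfite conversion is argued against, since the CC levels of 008-3 and 008-4 differed by 0.0516 points and their mCA by 0.938. An exchange of the labels of these 2 animals is a candidate explanation: 008-3 lay 0.0261 points from the mean of the other hKO animals, and 008-4 0.0381 points from that of the other WT animals. No biological explanation was tested, and a swap cannot be shown from methylation alone, so both animals stayed in the comparisons.

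The deposited CA value of WT striatum 602-2, 0.454%, lay far below the other WT striata (2.11% to 2.12%), and this library's mCG of 74.2% lay above theirs (71.3% to 71.6%). The CA and lambda cells of the library differ by 0, so a copied cell may explain the low value. A striatum with little non-CG methylation is argued against by its CT level of 0.7495%, near the mean of 0.803% in the other WT striata and above 0.316% in WT liver.

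WT construct libraries that share a code differed in mCA between title formats, for example 0.638% and 1.55% for 1 code, as did V665L (0.884% and 1.45%) and Y735C (0.831% and 1.46%). In WT construct libraries the CC level argues against incomplete conversion. Its mean difference was 0.00465 points where that of mCA was 0.636. Lambda was mixed and was not tested. In 1 code it was 1.03% at 1.41% mCA and 0.446% at 0.585%, with CC 0.0445 points apart. In another code it was 0.487% at 1.51% mCA and 0.485% at 1.05%. The V665L library at 1.45% mCA had a lambda of 1.07%. V665L and Y735C pairs were not tested, so incomplete conversion is not excluded there. A shift of all libraries of a format stays open: no-virus libraries differed 1.28-fold and knockout libraries 1.19-fold between the formats in which WT construct libraries differed 2.05-fold. V665L differed 1.76-fold (3 libraries each, of different codes), P904L 1.54-fold and M548K 1.09-fold, so the difference is not in WT construct libraries alone; the no-virus and knockout folds rest on 2 libraries on one side, and whether every library of a format shifted cannot be told. No biological explanation was tested.

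A sample lay far from its group in 21 of 201 groups of 4 to 10 values, where chance gives about 1 in 20, and groups sharing a library are not independent. Among cultures these were no-virus replicate 7 in mCA, 1.38% against 0.578% to 0.994%, and R749C replicate 3 in mCG, 70.05% against 73.4% to 75.8%. WT animal 651-3 was highest in mean gene mCA, 2.60% against 2.05% to 2.11%. It was also far above the other WT animals in mCA of Tet1 (3.11%), Meis2 (4.73%), Pcdhga11 (1.51%), Fosl2 (3.79%) and Rps6ka5 (3.41%). hKO animal 651-2 was far above the other hKO animals in Igf2r (1.77%), Reln (2.20%), Calb2 (2.17%), Acsbg1 (2.03%), Ptprc (1.85%), Nrxn3 (1.41%), Chd7 (3.70%) and Vmn2r1 (1.70%). Mean gene mCA of 651-2 was also the highest in hKO, 1.44% against 1.15% to 1.21%. Animals 651-2 and 651-3 share a title number. The genes named for them may therefore repeat a level of the whole library. hKO animal 694 was far above the others in Cml2 (3.32%), and hKO animal 047-1 was listed at 0 in Pcdhb9 mCG against 60.0% to 66.7%.

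The mCA difference between genotypes in points changed with age (permutation p = 1e-05, the smallest possible, with and without the 008 animals). As a ratio above CC, hKO to WT, it was 74.6% at 4 weeks and from 45.2% to 51.7% at the other ages after birth. At birth mCA lay above CC by less than the SD of that excess in each genotype, so no ratio can be read there. No change in proportion is therefore claimed. The mCA difference between genotypes differed between sexes in 2 genes, AC192923.1 and Atpif1 (limma, adjusted p = 0.0126 each). These calls rest on 2 animals per genotype and sex, and sex coincides with the instruments named in the labels. Of 21302 genes, 727 had an unadjusted limma p under 0.05 for this interaction. The hKO minus WT differences were -3.92 points in females and 0.0432 in males for AC192923.1, and -5.83 and 0 for Atpif1. In CT, a context outside the main comparisons, WT construct cultures held 0.531% and knockout cultures 0.369%, a difference of 0.162 points (permutation p = 0.00023).

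In mCA the real grouping gave 15376 genes and 15928 enhancers, and no other of the 35 splits of the 8 animals gave as many. The highest other split gave 11 and 6. For gene lists in mCA the real grouping was likewise 1 of 35, with 15 lists and none in any other split. Being 1 of 35 is the smallest share this design allows, so chance is argued against but not excluded. These calls also follow a shared shift of the library medians, so genes, enhancers and lists are not separate evidence. For mCG the splits decide nothing: the real grouping gave 0 genes, 0 enhancers and 0 lists, which all 35 splits must reach, and the highest other split gave 49, 6 and 13. For genes and enhancers that split was females against males, which points to a structure of the samples; sex and the instruments named in the labels coincide there. Within sex, 0 genes passed in mCG in males and 1 in females (1581 and 1522 at an unadjusted p under 0.05, limma).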

How the results depend on the processing

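Alternatives with the 008 animals or the CC level removed, with the repeated CA cell or lambda zeros kept, single sexes in the deep set, relative change with the CC level subtracted, and regions with a 0 left out were chosen after the results were seen; the others were planned. Of 1456 recomputed values, 1345 were labelled the same. For tests this meant the same direction and side of the threshold. For counts of calls and differences of deep from shallow libraries it meant a similar size. Of the 1108 values that left out 1 animal or library 1060 were the same, and of the 348 others 285. Where no cause is given below, the cause was not tested. Coverage minima and weights, filters on coverage, length or the X and Y chromosomes, and a block for cultures were not run, because no counts or mm9 annotation were used here and cultures share no replicate numbers. Unknown depth limits every value.

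Title numbers were not treated as pairs, since not every correlation passed 0.1: for 046, 047, 651 and the remaining 694 with 695, which share no number, they were 0.0841, 0.114, 0.0369 and 0.0386 in mCA and 0.0845, 0.0858, 0.1204 and 0.0389 in mCG. In mCA 5 of 8 animals and in mCG 6 of 8 correlated best with their own partner. The labels state littermates but give pairs only through title numbers, so the block was planned as an alternative. The cut-off of 0.1 was not part of that plan. The replicate block gave 16635 genes lower and 12 higher in mCA, 17 mCA lists lower, with protocadherins (fry, adjusted p = 0.0385) and vomeronasal receptors (0.0143) added, and 12 mCG lists lower where none was without it. Over all ages it gave -0.427 in mCA (permutation p = 0.00791) and -1.72 in mCG (0.00394). With the block, 8-week mCA differed by -1.02 (exact p = 0.5, 2 animals per genotype), 2-week mCA by -0.485, liver mCG by 0.0854, and deep means by -0.960 in genes and -1.05 in enhancers (exact p = 0.125, the smallest possible).

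With lambda subtracted, mCA at birth was -0.0272 (-0.00851 with CC subtracted), and differences from knockout were 0.0276 for W297del, 0.0114 for S312fs11x, 0.0372 for M548K, -0.0211 for R749C and -0.0132 for P904L; W297del minus WT construct mCG was 0.00798. Males alone gave -0.501 at 2 weeks, and females alone -1.92 in mCG over ages. Each library as its own sample gave -3.88 for 8-week mCG (permutation p = 0.0453, adjusted 0.272). With codes averaged, V665L minus knockout was 0.223 and W297del minus WT construct mCG 0.190. Within title format, W297del minus knockout was -0.0764, and mCG differences were -0.227 (S312fs11x) and -0.0934 (R749C) from knockout and 0.0615 (M548K) and -1.31 (R749C) from WT construct. Medians gave -0.0843 (W297del) and -0.0158 (R749C) from knockout, -0.651 (S312fs11x), -0.467 (G532S) and -0.596 (P904L) from WT construct, and in mCG -0.439 (P904L from knockout) and -0.492 (R749C from WT construct).

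In deep libraries, males alone gave -0.858 (genes) and -0.923 (enhancers) and females alone -1.06 and -1.17, with 2 animals per genotype, too few to pass. Relative change between level quartiles was -10.4 in genes and -4.76 in enhancers, and -4.59 and 0.132 with the shallow CC level of each genotype subtracted. Medians removed gave 5283 lower and 6523 higher genes, 43 and 237 enhancers, 6 and 8 mCA lists, and 2 mCG lists higher. Higher genes numbered 2 without regions holding a 0, 54 in males and 27 in females, where 7841 were lower; higher enhancers were 1 without zeros and 1 on the logit scale, and 0 lower and 0 higher passed in either sex (limma, 11595 and 11216 unadjusted); 1 mCG gene was higher in females. Camera gave 3 lower and 5 higher mCA lists preset, 0 lower estimated, and 1 lower and 3 higher in mCG. At the estimated correlation, protocadherins were higher in mCA without 651-2 (adjusted p = 0.0499) and with the block (0.0474), olfactory genes in mCG with the block (0.0432) and vomeronasal genes in mCG with medians removed (0.0411).

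Leaving out 1 animal or library gave ranges of -4.80 to -2.79 (8-week mCG, past the unadjusted threshold without 726, adjusted p = 0.141), -0.00699 to 0.0362 (mCA at birth), -1.87 to 0.550 and -3.04 to 0.0528 (mCG at birth and 1 week), -0.746 to -0.235 (4-week mCA), -2.47 to 0.718 (liver mCG), -0.0573 to 0.0101 (S312fs11x minus knockout), -0.375 to -0.239 (V665L minus WT construct, past the threshold without V665L replicate 3, adjusted p = 0.0336) and -0.0940 to -0.0696 (W297del minus knockout, lost without W297del replicates 1, 2, 4 or 5). mCG from WT construct ranged from -1.31 to 0.388 (M548K), -0.306 to 0.717 (R749C), -1.01 to 0.217 (S312fs11x) and -0.426 to 0.290 (W297del), and the enhancer mCG level difference from 1.62 to 2.22. Higher mCA genes ranged from 3 to 21, enhancers from 7001 to 16627 lower and 0 to 3 higher, and mCG genes in each direction, lower enhancers and lower lists from 0 to 1.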

Other observations

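The values here, the comparisons by sex and of lambda, and the comparison with cultures without virus were chosen after the data had been seen.

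Subtracting the CC level, mCA of hKO cortex was 0.00886 points at birth against 0.0174 in WT, 0.0887 against 0.196 at 1 week, 0.516 against 1.04 at 2 weeks, 1.23 against 1.65 at 4 weeks, 1.07 against 2.07 at 8 weeks and 0.989 against 2.02 at 20 weeks. In striatum the values were 0.946 and 1.80, in hippocampus 0.639 and 1.22, in cerebellum 0.431 and 0.841, and in liver 0.0332 and 0.109. CT methylation of 8-week cortex was 0.541% in hKO (n = 7) and 0.891% in WT (n = 11; exact permutation p = 3.14e-05, the smallest possible), and CC was 0.267% and 0.362% (exact permutation p = 0.00600, adjusted 0.0360). At 0, 1, 2, 4 and 20 weeks CC differed by 0.0166, 0.0131, 0.0162, -0.00595 and -0.0326 points and did not pass (exact permutation p = 0.268, 0.6, 0.643, 0.875 and 0.2), and 3 libraries of WT animal 046-1 spanned 0.332% to 0.413%.

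With sex as the compared factor in the deep libraries, 42 genes differed in mCG, 38 higher and 4 lower in females (limma, adjusted p under 0.05). They include the X-linked Gpr101 (73.7% in females, 28.3% in males) and Kdm6a (84.6% and 76.8%), and the Y-linked Rbmy1a1 (3.12% and 74.5%). Females carry no Y chromosome, so the female value of Rbmy1a1 is not a level of that gene, although it counts among the 4 lower ones. In mCG 7369 of 21060 genes had an unadjusted limma p under 0.05. Mean gene mCG was also higher in females, 77.8% against 74.5% in WT and 75.2% against 72.7% in hKO. A shift of whole libraries can therefore not be told apart from gene differences in these calls. The 42 genes were not divided by chromosome. In mCA limma called 0 genes, with 1910 at an unadjusted p under 0.05. Sex coincides with the instruments named in the labels.

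Lambda in 8-week cortex was 0.439% in hKO (n = 7) and 0.527% in WT (n = 11) with exact zeros treated as missing (difference -0.0883 points, exact permutation p = 0.0593). With the zeros kept as deposited, hKO was 0.392% and the difference -0.135 points (exact permutation p = 0.0173).

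The WT construct exceeded cultures without virus by 0.256 points in mCA (permutation p = 0.0506; within title format 0.243 points, p = 0.0450). Of the 2 cultures whose title and genotype label disagree, the one titled as knockout held 0.947% mCA and the one titled as without virus 0.476%.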
